A study of Mus musculus with 26 samples.

How the data were processed

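The samples were 26 pools of 100 starburst amacrine cells sorted from C57BL/6 mouse retinas at embryonic day 17.5, 13 heterozygous and 13 homozygous for a GFP allele of Fezf1. Libraries were made with Smart-seq2, which copies full-length polyadenylated RNA into cDNA and carries no molecular identifiers, and with Nextera XT, per the labels' protocols, and were sequenced as paired ends on an Illumina NextSeq, per the series' design text. TopHat2 2.0.10, Cufflinks (version not given) and the mouse build mm10 are named per the submitters' processing notes. The gene annotation, the filters and the way TPM was derived from those tools' output are not given in the sources used here.

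The deposited table holds log10 values, which the authors computed as log10(TPM + 1): the base and the offset were found from the values, since raising 10 to each value and subtracting 1 gave a sum of 1000000 in every pool. The table has 24883 rows and 24346 gene symbols. The 817 rows that share 280 symbols were summed in TPM for each symbol. TPM is relative to all transcripts of a pool, so a transcript that takes a large share lowers every other value. In Het pool 12 Mir181a-2 alone took 28.0% of the TPM. TPM keeps no read counts, so the depth of each pool is unknown and no counting interval was possible. Some values of 0 may be failed estimates: each pool listed between 2 and 100 genes at 0 whose median in the pool's own group was 10 TPM or more, and 1 of 10 housekeeping genes checked was listed at 0 in at least 1 pool. Of the changed genes, 9 had such a 0.

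Values were returned to TPM and tested as log2(TPM + 1), on which a fold change understates the change of low genes. Genes at 1 TPM or more in at least 7 of the 26 pools, counted without regard to genotype, were tested, which left 12406. The test was limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with genotype alone in the model and a Benjamini-Hochberg adjusted p under 0.05 over all tested genes as the threshold. Changes are KO minus Het on this log2 scale. Unadjusted p under 0.05 were found for 1188 genes, where 620 are expected without any change, and the median change of all genes was 0.033. The tables were handled in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

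Groups were taken from the genotype in the labels. The labels do not say whether pools of a genotype came from separate embryos, so the p-values measure the spread between pools, which may be partly technical. The pools were compared before they were averaged: no pair shared more than 0.0242% of its nonzero values within a tolerance of 1e-09. The correlation across genes within a genotype and run lay between 0.857 and 0.947 (median 0.93, against 0.874 for other pairs). No pool was a copy of another, so each was kept as a replicate, but this does not show that the pools are independent. By Xist and the Y-linked genes, all pools of a genotype and run had a single sex, so they may share embryos. Sample sizes here count pools. Because the last run of pool numbers differed from the others, values are given within runs and with the run as a block.

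The test, the gene filter, the gene lists, the rule for named genes and the main alternatives were fixed before the data were examined. The named genes were Fezf1, Rnd3, Sema6a and the starburst cell list, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, changed by at least 1 and with a mean of at least 3 on the log2 scale in a group, and then up to 4 called members of each list with the smallest adjusted p. That rule met 50 genes higher and 52 lower in KO, and predicted genes were left unnamed. The ganglion cell genes given as examples were chosen after their values were seen. The 29 lists covered starburst cells, amacrine and GABA genes, other amacrine subtypes, retinal ganglion cells, progenitors and glia, the cell cycle, neurogenic progenitors, photoreceptors, bipolar cells, horizontal cells, blood, vessels and microglia, pigment cells and lens, and the Rho family and migration. They also covered axon guidance, cadherins, immunoglobulin and leucine-rich repeat adhesion, retinal transcription factors, ion channels, neurotransmitter receptors, synaptic vesicles, the Notch, TGF-beta and BMP, Wnt, and FGF and growth factor pathways, immediate early and heat shock genes, cell death, mitochondrially encoded, ribosomal protein and sex-linked genes. The 28 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation, with fry for a shared direction and for mixed directions, and with the run as a block. A one-sided Fisher's exact test of called genes against all tested genes was added after the data were seen.

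Principal components were taken from the 1000 most variable genes, and permutation tests used 100000 resamples and were two-sided. The alternatives fixed beforehand were other offsets, filters, scalings and variance models, pool quality weights, a rank-sum permutation test, the run or the number of detected genes in the model, the removal of runs and of single pools, and a minimum change of 0.5. Single runs, 6 means, correlated pools, removal of abundant small RNA and Rn45s, covariates for Xist and for the ganglion cell genes, the latter also for the second principal component, and removal of 4 pools that stood apart were added after the data were seen. The pipeline was tested on simulated data for the comparison of KO with Het, with the real means and spreads of the 12406 genes and 200 genes changed in each of 5 draws. It recovered 11.6% of changes of 0.5, 52.8% of changes of 1 and 91.1% of changes of 2 on the log2 scale, and 1.1% of its calls were false. With the run as a block it recovered 24.4%, 63.9% and 95% of them, and 3.8% of its calls were false. The simulated noise was independent between pools and between genes. The false shares therefore do not cover effects shared by pools of an embryo or by genes of a cell type.

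Gene positions are from the GENCODE annotation of GRCm38, the assembly that mm10 names, in which 12281 of the 12406 tested symbols (99.0%) matched a single gene. The strandedness of the libraries is not stated, so reads in exons that overlap another gene cannot be told apart. Among the named genes this concerns Prox1 (with Prox1os), Grm8 (with Mir592), and Ache, Tenm3, Cftr, Plagl1, Syt4, Maml2, Fst and Gfra1, each with a predicted gene.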

Results

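RNA was measured in 26 pools of 100 starburst amacrine cells, sorted by fluorescence from mouse retinas at E17.5, late in embryonic development. Starburst amacrine cells are the cholinergic interneurons of the retina, and they occur as ON and OFF types that sit in different cell layers. 13 pools came from heterozygous retinas carrying a GFP allele of Fezf1 (Het), and 13 came from retinas homozygous for that allele (KO). Fezf1 encodes a zinc finger transcription factor, and the comparison of KO with Het asked what its loss does to the transcripts of these cells in a study of the choice between the ON and OFF fates. The labels did not say which starburst cells the sorting gate held, nor whether the pools of a genotype came from different embryos. A pool had between 10565 and 11910 genes at 1 or more TPM, each transcript's length-corrected share of the pool's total (11377 ± 305, SD, n = 26), and its read depth is unknown because TPM keeps no depth.

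The pool numbers fell into 3 runs, each holding as many KO as Het pools: pools 1 to 12, 13 to 18 and 19 to 26. The last run stood apart. The ribosomal RNA precursor Rn45s took 2.26% ± 0.715 of the TPM in its 8 pools (SD, n = 8) and 12.4% ± 2.04 in the other 18 (SD, n = 18). Rn45s did not separate the genotypes, at 9.42% ± 5.30 of the TPM in Het and 9.12% ± 5.04 in KO (SD, n = 13 each). Transcripts of the sex chromosomes also followed the runs. Xist, which is transcribed from the inactive X chromosome, was above 20 TPM in 13 pools, and the sum of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was above 20 TPM in the other 13. In the first 2 runs the Xist pools were the KO pools, and in the last run they were the Het pools.

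Fezf1 transcripts were nearly absent from the KO pools. Fezf1, on chromosome 6 at 23245044 to 23248362 of GRCm38, was at 264 ± 42.8 TPM in Het and at 0.711 ± 0.772 TPM in KO (SD, n = 13 each). Each KO pool, the highest at 2.86 TPM, lay below each Het pool, the lowest at 186 TPM, so the labels and the targeted gene matched in all 26 pools. The log2 change, KO minus Het, was -7.37 (SE 0.18, limma adjusted p = 1.64e-23), and a two-sided permutation test gave p = 1e-05, the smallest its 100000 resamples can give.

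Rnd3 moved the opposite way. Rnd3 encodes an atypical Rho GTPase and is known as a marker of OFF starburst cells. It lies on chromosome 2 at 51130438 to 51149111 and stood at 137 ± 45.6 TPM in Het and 902 ± 146 TPM in KO (SD, n = 13 each). The log2 change was 2.75 (95% interval 2.49 to 3.02, limma adjusted p = 1.26e-15, permutation p = 1e-05), and all 13 KO pools lay above all Het pools. The rise was 2.76, 3.13 and 2.46 on the log2 scale in the 3 runs. Sema6a, a transmembrane semaphorin that is known to differ between ON and OFF starburst cells, was at 35.4 ± 13.3 TPM in Het and 45.5 ± 12.2 TPM in KO, a log2 change of 0.37 with an interval of -0.03 to 0.77 that did not pass the test (adjusted p = 0.582).

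**Figure D1:**
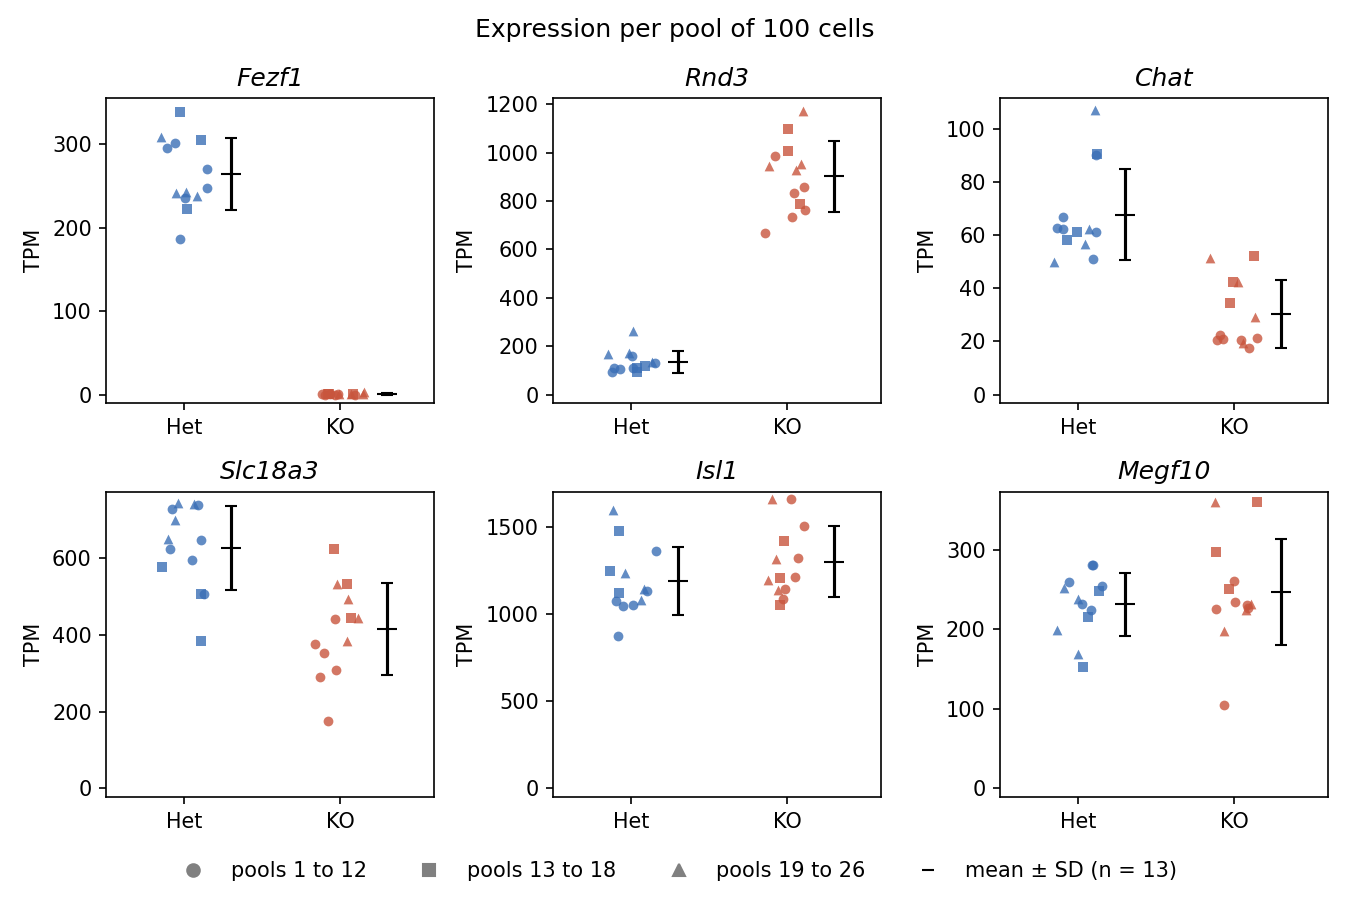
Expression of 6 genes in TPM (vertical axes, from 0) in each pool of 100 cells, Het in blue and KO in red, with the mean ± SD of 13 pools beside each group and marker shapes for the 3 runs of pool numbers. Fezf1 lies at or below 2.86 TPM in KO, Rnd3 lies at or above 666 TPM in KO, Chat and Slc18a3 are lower in KO, and the changes of Isl1 and Megf10 did not pass the test.

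Chat, Slc18a3 and Slc10a4, genes of acetylcholine synthesis and storage, fell in KO, while the changes of Isl1, Sox2, Megf10 and Megf11 did not pass the test. Chat, which makes acetylcholine, fell from 67.7 ± 17.2 to 30.3 ± 12.7 TPM (SD, n = 13 each), a log2 change of -1.20 (SE 0.18, adjusted p = 6.63e-05). Slc18a3, the vesicular acetylcholine transporter gene, fell by 0.63 on the log2 scale (adjusted p = 0.0146), and Slc10a4, another gene of cholinergic synaptic vesicles, fell by 0.53 (adjusted p = 0.00521). In the separate runs the log2 change of Chat was -1.61, -0.69 and -0.96, and that of Slc18a3 was -1.02, 0.13 and -0.62. Without pools 1 to 12 all 3 calls were lost, at log2 changes of -0.84 for Chat (SE 0.24, adjusted p = 0.184), -0.30 for Slc18a3 (SE 0.16, adjusted p = 0.612) and -0.59 for Slc10a4 (SE 0.16, adjusted p = 0.135). The call of Slc10a4 was also lost without pools 13 to 18 (adjusted p = 0.0572) and that of Slc18a3 without pools 19 to 26 (adjusted p = 0.0790). The fits without a run had genotype alone in the model, so differences between the remaining runs entered their SE. With the run and the mean of 14 ganglion cell genes in the model, the changes of Chat, Slc18a3 and Slc10a4 were -1.11 (SE 0.19, adjusted p = 0.000645), -0.52 (SE 0.16, adjusted p = 0.141) and -0.41 (SE 0.11, adjusted p = 0.0746), against SE of 0.16, 0.14 and 0.10 with the run alone, so the calls of Slc18a3 and Slc10a4 were lost. Slc18a3 lies at 32462438 to 32464850 on chromosome 14, inside the span of Chat at 32408203 to 32465989 on the same strand. Ache, which breaks down acetylcholine, rose by 1.97 (SE 0.52, adjusted p = 0.0418).

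The transcription factor genes Isl1 and Sox2 and the receptor genes Megf10 and Megf11, which mark starburst cells, had log2 changes of 0.13, -0.18, 0.06 and -0.16, with adjusted p of 0.798, 0.695, 0.999 and 0.927. Isl1 was at 1190 ± 196 TPM in Het and 1304 ± 206 TPM in KO, and the interval of its change was -0.06 to 0.32. The guidance receptor gene Plxna2 had a log2 change of -0.12 (adjusted p = 0.963), and Slc5a7 was at 0.150 TPM in Het and 0.619 TPM in KO and too low to test. Of the 10 starburst cell genes tested, 1 rose and 3 fell over all genes, and the counts adjusted over the list alone were also 1 and 3. The list was lower by limma's camera test (median log2 change -0.14, adjusted p = 0.0394), a call that was lost at an adjusted p = 0.587 with an estimated correlation. That camera call was also lost with the run as a block (adjusted p = 0.0555) and on 6 means, 1 for each genotype and run (adjusted p = 0.327). Called genes were over-represented in the list by a one-sided Fisher's exact test (adjusted p = 0.000270).

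The mean of the retinal ganglion cell genes was higher in the KO pools, while tests of the list as a set differed. The mean of the 14 tested ganglion cell genes was 5.93 ± 0.90 in KO and 4.92 ± 1.04 in Het on the log2(TPM + 1) scale (SD, n = 13 each). The difference was 1.01 (permutation p = 0.0149, not adjusted for the other lists), and it was 0.834, 0.986 and 1.28 in the 3 runs. Examples are Sncg, at 312 TPM in Het and 780 TPM in KO, Pou4f3, at 36.4 and 90.3 TPM, and Rbpms2, at 25.6 and 65.1 TPM. None passed limma's test over all genes, 10 had an unadjusted p under 0.05, the rank-sum test called 0 and the model with the run as a block called 3. Adjusted over the list alone, 8 rose and 1 fell, namely Pou6f2, at 266 TPM in Het and 182 TPM in KO (log2 change -0.57, SE 0.16, adjusted p over all genes = 0.0590). The camera test placed the list higher in KO (adjusted p = 0.000784). With the run as a block (adjusted p = 0.00359) and on 6 means (adjusted p = 6.18e-12) it also did so. Both fits kept the preset correlation of 0.01, while the estimated correlation of this list was 0.551. They are therefore no separate support, because they treat its genes as nearly independent. The call was lost with an estimated correlation (adjusted p = 0.587), and fry's directional test of the list did not pass (adjusted p = 0.365). With the mean of these genes as a covariate beside the run, the log2 change of Ache went from 1.97 (SE 0.52) to 0.65 (SE 0.42, adjusted p = 0.777). Of the genes named here as changed, 13 lost their call with that covariate. Ache, Irx4 and Cacng5 kept 32.9%, 42.9% and 34.4% of their change, while the other 10, Slc10a4, Slc18a3, Ccdc85c, Foxn4, Th, Robo1, Cdh6, Tshz3, Kcng3 and Gabrd, kept 68.3% to 93.2%.

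Across the 12406 genes tested, 222 changed between KO and Het, 109 rising and 113 falling. Of these, 144 changed by 1 or more on the log2 scale, 74 up and 70 down. In 22 of the 222 genes all KO pools lay beyond all Het pools. Chance gives this in 1.92e-05% of genes if the pools are independent. The 22 were counted among genes called from the same values, so the count is not separate support. The direction was the same in all 3 runs for 216 of the 222 genes. That count too comes from genes called from the same pools, so it is not separate support. With the run as a block, limma called 348 genes, 189 higher and 159 lower, and these included all 222. Within single runs it called 215, 65 and 19 genes, from 12, 6 and 8 pools, of which 113, 34 and 11 were among the 222.

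**Figure D2:**
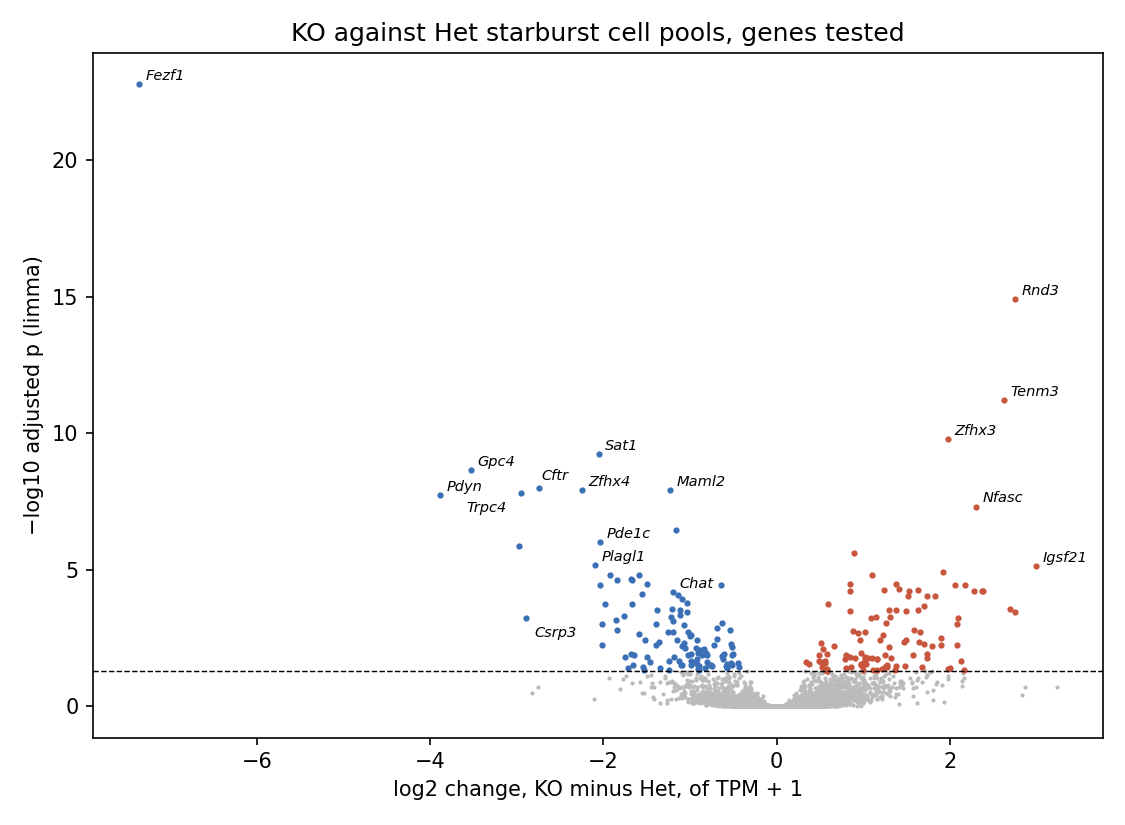
Each point is 1 of the 12406 genes tested, with the log2 change of TPM + 1, KO minus Het, on the horizontal axis and minus log10 of the limma adjusted p on the vertical axis; red genes were higher in KO, blue genes were lower in KO and grey genes did not pass the threshold of 0.05 (dashed line). Fezf1 and Rnd3 have the smallest adjusted p, 1.64e-23 and 1.26e-15, at log2 changes of -7.37 and 2.75.

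The largest rises were in Igsf21, Caly, Rnd3, Tgfbi and Tenm3. Igsf21, a synaptic immunoglobulin protein gene on chromosome 4, rose from 15.95 ± 10.97 to 101 ± 27.1 TPM, a log2 change of 3 (SE 0.38, adjusted p = 7.16e-06). Tenm3, a teneurin gene on chromosome 8, rose by 2.62 (SE 0.17, adjusted p = 6.25e-12), from 4.22 ± 1.41 to 30.6 ± 6.12 TPM, with all 13 KO pools above all Het pools. Nfasc, which encodes the adhesion protein neurofascin, rose by 2.30, the planar polarity gene Prickle1 by 2.28 and the laminin chain gene Lamb1 by 2.18. The matrix protein gene Tgfbi rose by 2.70, the protease inhibitor gene A2m by 2.37 and Caly, a gene of vesicle trafficking, by 2.76. The homeobox genes Prox1, Irx4 and Zfhx3 rose by 2.09, 2.13 and 1.98, and Ccdc85c rose by 2.16 (adjusted p = 0.0444). The rise of Prox1 was 0.83, 2.96 and 3.35 in the 3 runs. Zfhx3 was at 8.83 ± 2.16 TPM in Het and 37.4 ± 6.48 TPM in KO, without overlap of the pools. Irx4 and Caly moved with the ganglion cell genes: with that covariate their log2 changes were 0.91 (SE 0.32, adjusted p = 0.269) and 1.79 (SE 0.45, adjusted p = 0.0354).

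The largest falls after Fezf1 were in Pdyn, Gpc4 and Trpc4. Pdyn, the gene of the opioid peptide precursor prodynorphin, fell from 91.7 ± 21.2 to 8.60 ± 11.7 TPM, a log2 change of -3.89 (SE 0.37, adjusted p = 1.89e-08). The glypican gene Gpc4 fell by 3.53, from 15.5 TPM to 0.391 TPM, and was listed at 0 in 9 KO pools. The cation channel gene Trpc4 fell by 2.96, the muscle LIM protein gene Csrp3 by 2.89 and the chloride channel gene Cftr by 2.74. Zfhx4, a homeobox gene on chromosome 3, fell by 2.25, from 28.04 ± 5.57 to 5.45 ± 2.42 TPM, opposite to Zfhx3. Plagl1, a zinc finger gene, fell by 2.09, Sat1, which acetylates polyamines, by 2.06, Prr5, a gene of the mTOR complexes, by 2.04, the phosphodiesterase gene Pde1c by 2.04 and the glutamate transporter gene Slc1a6 by 2.01. In Pdyn, Gpc4, Trpc4, Cftr, Zfhx4, Plagl1, Sat1 and Pde1c all 13 KO pools lay below all Het pools. Gpc4 and Sat1 are on the X chromosome, and in the last run, where the Het pools held Xist, their log2 changes were -2.97 and -2.04.

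Among 74 tested adhesion genes of the immunoglobulin and leucine-rich repeat families, 7 rose and 2 fell. Adjusted over the list alone, 10 rose and 6 fell. Besides Igsf21, Tenm3 and Nfasc, the contactin gene Cntn4 rose by 1.49 (adjusted p = 0.00367). Called genes were over-represented in this list (Fisher's exact test, adjusted p = 0.000180), while its camera test did not pass (adjusted p = 0.331). Of 56 axon guidance genes, 4 rose and 2 fell, and 8 and 3 did when adjusted over the list alone. The semaphorin genes Sema6d and Sema7a rose by 2.06 and 1.10, the receptor gene Robo1 rose by 1.02, and Slit2, which encodes a ligand of Robo1, fell by 1.49, from 37.5 ± 15.4 to 12.5 ± 4.54 TPM. Called genes were over-represented here too (Fisher's exact test, adjusted p = 0.00441; camera adjusted p = 0.700). With the ganglion cell genes as a covariate the change of Robo1 went from 1.02 (SE 0.25) to 0.78 (SE 0.28, adjusted p = 0.295). Of 87 cadherins and protocadherins, Pcdh9 and Cdh6 fell, by 0.69 and 0.75, and none rose by limma's test, with 5 higher at an unadjusted p under 0.05. The counts adjusted over the list alone were also 0 and 2, the list's camera adjusted p was 0.381, and Cdh6 had a log2 change of 0.07 in the last run.

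Genes of transcription and excitability went both ways. Of 62 retinal transcription factor genes, Zfhx3 and Irx4 rose and Zfhx4 and Tshz3 fell, and adjusted over the list alone 8 rose and 5 fell (camera adjusted p = 0.700). Tshz3, a zinc finger homeobox gene, fell by 0.93, with log2 changes of -0.96, 0.03 and -1.61 in the 3 runs. Of 89 ion channel genes, Cacng5 rose by 1.37 while Trpc4 and Kcng3 fell, the latter by 0.99 from a level of 1.41 TPM, and adjusted over the list alone 2 rose and 4 fell (camera adjusted p = 0.700). With the ganglion cell covariate the change of Cacng5 went from 1.37 (SE 0.34) to 0.47 (SE 0.27, adjusted p = 0.711). Of 41 neurotransmitter receptor genes, the glutamate receptor genes Grik2 and Grm8 rose by 1.09 and 1.26, while the GABA receptor gene Gabrd and the adrenergic receptor gene Adra1a fell by 0.82 and 1.98. In the 3 runs Gabrd changed by -0.52, -0.36 and -1.6, and Adra1a by -2.59, -2.48 and -0.71. Adjusted over the list alone 5 rose and 4 fell (camera adjusted p = 0.966), and called genes were over-represented (Fisher's exact test, adjusted p = 0.0421). Of 46 synaptic vesicle genes, Syt4 rose by 1.37 (adjusted p = 3.23e-05; 0.99, SE 0.19, adjusted p = 0.00273, with the ganglion cell covariate). Adjusted over the list alone 3 rose and 0 fell, with 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.675).

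In the signalling lists the counts were small. Of 41 genes of the FGF and growth factor pathways, 3 rose: Igfbpl1 by 1.41, the GDNF receptor gene Gfra1 by 1.30, and Dusp6, a phosphatase gene known to be switched on by FGF signalling, by 1.24 (adjusted p = 5.64e-05), with all 13 KO pools above all Het pools. None fell over all genes, and 4 rose and 1 fell when adjusted over the list alone. The camera test placed the list higher (adjusted p = 0.0488), which was lost at an adjusted p = 0.587 with an estimated correlation. That camera call was also lost with the run as a block (adjusted p = 0.0555) and on 6 means (adjusted p = 0.0746). Of 22 Notch pathway genes, the coactivator gene Maml2 fell by 1.23, from 69.6 ± 14 to 28.9 ± 4.15 TPM (adjusted p = 1.18e-08), and Maml3 rose by 0.58 (adjusted p = 0.0498). Adjusted over the list alone, 1 rose and 3 fell (camera adjusted p = 0.295). Of 36 genes of the TGF-beta and BMP pathways, the ligand gene Bmp2 rose by 1.92, from 0.240 to 4.03 TPM, and Fst, which encodes the antagonist follistatin, fell by 1.77 and was listed at 0 in 12 KO pools. Adjusted over the list alone, 4 rose and 3 fell (camera adjusted p = 0.700). Of 19 Wnt pathway genes limma called 0 over all genes and 0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 0 by the rank-sum test (camera adjusted p = 0.700). Of 31 genes of the Rho family and neuronal migration, Rnd3 rose and 0 fell, with 1 lower at an unadjusted p under 0.05, and 3 rose when adjusted over the list alone. This list passed the camera test as higher (adjusted p = 0.0488). Its call was lost with an estimated correlation (adjusted p = 0.859) and with the run as a block (adjusted p = 0.102). On 6 means it passed (adjusted p = 0.0462).

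Genes of other amacrine types and other retinal cells gave few calls. Of 15 amacrine and GABA genes, the transcription factor gene Foxn4 fell by 1.46, from 4.66 to 0.889 TPM (adjusted p = 0.0228), and 4 fell when adjusted over the list alone. The list was lower by the camera test (adjusted p = 0.0394), which was lost at an adjusted p = 0.587 with an estimated correlation. That camera call was also lost with the run as a block (adjusted p = 0.0614) and on 6 means (adjusted p = 0.148). Of 10 genes of other amacrine subtypes, Th, the gene of dopamine synthesis, fell by 1.54 (adjusted p = 0.0370), and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.700). Of 8 horizontal cell genes, Prox1 rose, and 3 rose when adjusted over the list alone. The horizontal cell list was higher by camera (adjusted p = 0.0394). Its call was lost with an estimated correlation (adjusted p = 0.587) and with the run as a block (adjusted p = 0.0555). On 6 means the horizontal cell list passed (adjusted p = 0.0360). The 22 cell cycle genes were lower by camera (median log2 change -0.22, adjusted p = 0.0394). Their call was lost with an estimated correlation (adjusted p = 0.587) and with the run as a block (adjusted p = 0.0555). On 6 means the cell cycle list passed (adjusted p = 0.0360).

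Limma called 0 genes in the lists of retinal progenitors and glia (15 tested), the cell cycle (22), neurogenic progenitors (11), bipolar cells (4) and pigment cells and lens (3), over all genes and adjusted over the list alone. Of these 55 genes, 6 had an unadjusted p under 0.05, and the rank-sum test and the run block called 0. Apart from the cell cycle list, their camera adjusted p were 0.299, 0.966, 0.579 and 0.700. Limma called 0 of 7 photoreceptor genes and 0 of 3 genes of blood, vessels and microglia over all genes, and adjusted over the list alone 1 rose in each, as did 1 in each at an unadjusted p under 0.05 (rank-sum test 0, camera adjusted p = 0.700 for both).

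Lists that report on RNA quality gave 0 calls over all genes by limma. The 81 ribosomal protein genes had a median log2 change of 0.14 and were higher by camera (adjusted p = 0.000558), which was lost at an adjusted p = 0.900 with an estimated correlation. Camera also placed these genes higher with the run as a block (adjusted p = 2.41e-05), while on 6 means they did not pass (adjusted p = 0.282). Of these genes 0 were called over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05 and the rank-sum test called 0. Of the 19 immediate early and heat shock genes and the 16 cell death genes, limma called 0 over all genes and adjusted over the list alone, with 5 at an unadjusted p under 0.05, 0 by the rank-sum test and 2 with the run block (camera adjusted p = 0.295 and 0.966). On 6 means, 1 for each genotype and run, camera placed the immediate early and heat shock list higher in KO (adjusted p = 0.0360; the median log2 change over the 26 pools was 0.208). Of the 6 sex-linked genes 0 passed over all genes or by the rank-sum test, 5 had an unadjusted p under 0.05, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.295). The table listed 0 mitochondrially encoded genes. Of all lists, the sign of the median differed from that of the mean for the Wnt list (-0.073 and 0.044) and the list of blood, vessels and microglia (0.152 and -0.081), and the ion channel list had a median of 0.044 with a camera direction that was lower.

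The genotypes were also separate in a principal component analysis of the 1000 most variable genes. The first component held 25.2% of the variance and followed the runs, which accounted for 98.5% of it. The second held 9.2%, and on it the KO pools lay at 13.05 ± 5.5 and the Het pools at -13.05 ± 8.1 (SD, n = 13 each; permutation adjusted p = 5e-05 over 5 components, the smallest its resamples can give). On that component the lowest KO pool was at 2.73 and the highest Het pool at -0.62. This component also followed the mean of the ganglion cell genes within genotype and run (correlation 0.913, n = 26 pools). With the run in the model the difference between KO and Het on it was 26.11 (SE 2.82), and with the ganglion cell mean added it was 19.19 (SE 1.96).

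**Figure D3:**
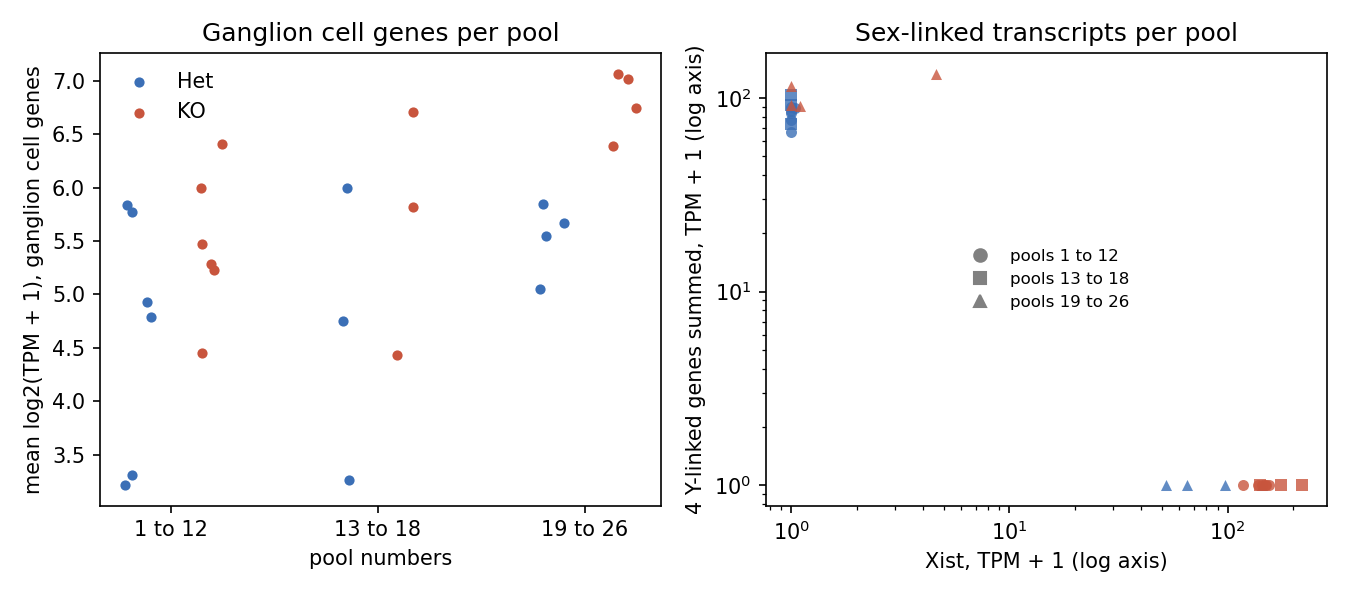
The left panel gives the mean log2(TPM + 1) of 14 ganglion cell genes for each pool, by run of pool numbers, with Het in blue and KO in red; the KO means exceed the Het means by 0.834, 0.986 and 1.28. The right panel gives Xist against the sum of 4 Y-linked genes, in TPM + 1 on log axes with a marker shape for each run; 13 pools held Xist above 20 TPM, the other 13 held the Y-linked sum above 20 TPM, and the genotypes trade places in the last run.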

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

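The test of a different genotype effect between runs, the tests of sex, the splits within runs and the fit to 6 means were chosen after the results were seen, although the bounds for the last 2 were written before they were run, and the test by splits of all pools was planned. The difference between KO and Het itself differed between the 3 runs of pool numbers for 26 genes by an interaction term in limma, with 1343 genes at an unadjusted p under 0.05. Of the 26 genes, 6 are on the X or Y chromosome, 0 are genes named by the rule, and 1, the predicted gene 3110039I08Rik, is among the 222 genes changed overall. The interaction was strongest for Eif2s3y (adjusted p = 1.79e-20), with log2 changes of -5.86, -6.09 and 6.49 in the 3 runs, and for Xist (adjusted p = 6.12e-17), with changes of 7.13, 7.46 and -5.79. Ddx3y (adjusted p = 4.87e-12), Kdm5d (adjusted p = 6.49e-08) and Uty (adjusted p = 9.65e-06) were lower in KO in the first 2 runs and higher in the last.

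A difference in the sex of the embryos, tied to genotype within each run, is in line with these genes: all 6 sex-linked genes of the list had opposite directions in pools 1 to 18 and pools 19 to 26. Sex is argued against for most autosomal changes called from pools 1 to 18. Of those 224 genes, 204 (91.1%) had the same direction in pools 19 to 26, where the sexes of the genotypes were exchanged. For the rest, which reversed, sex stays open, and the 222 genes were not tested as a set in this way. Of the 10 other X-linked genes called from pools 1 to 18, 10% (1 gene, Dmrtc1a) reversed, and Gpc4 and Sat1 did not; an undivided test of all 16 X- and Y-linked genes, of which 7 reversed, had not decided the question and was replaced by these. Chance assignment of single pools is argued against. Among 100 splits of the 26 pools 1, the real one with 222 genes, gave as many calls, and the highest other gave 1. Those splits ignored the runs. Among 100 splits within the runs, with the run as a block, also only the real one with 348 genes gave as many. The highest other gave 2. All these splits exchange single pools, so they cannot exclude chance differences between embryos if pools share embryos. A few embryos that differ by chance could also give calls, but 185 genes passed when each genotype and run counted as 1 sample. Of these, 122 were among the 222, and for the rest of the 222 the fit gave no call. The mean of the ganglion cell genes was higher in KO in each run, by 0.834, 0.986 and 1.28, and such a difference can pass this fit too. Apart from Fezf1, the targeted gene, the genotype stays open as a hypothesis for the 122 genes. The fit does not tell a change within the cells from a different share of ganglion cell RNA.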

How the results depend on the processing

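The settings of single runs, 6 means, correlated pools, removal of Rn45s and small RNA, the Xist and ganglion cell covariates, removal of 4 pools, over-representation and the scalings of the list tests were chosen after the results were seen. The log2 changes of Fezf1 and Rnd3 kept their direction and passed the threshold in every setting run, and the means of the genotypes differed on a principal component with 500 genes and with all tested genes; the pools did not overlap with 500 genes but did with all of them (lowest KO pool -10.67, highest Het pool 25.26). The count of 222 changed genes became 348 with the run as a block, 428 with pool quality weights and 466 with the run block and Xist as covariates. In simulated data the run block raised the recovery of changes of 1 from 52.8% to 63.9% and the false share of calls from 1.1% to 3.8%; otherwise the cause was not tested. The count became 66 without pools 1 to 12 and 136 without pools 13 to 18, 65 in pools 13 to 18 alone and 19 in pools 19 to 26 alone. The fits without a run had genotype alone in the model, so differences between the remaining runs entered their spread. Otherwise the cause of these lower counts was not tested. With a minimum change of 0.5, a stricter test, the count was 53. Leaving out 1 pool at a time gave 191 to 262. The remaining settings gave 175 to 288 genes, among them 284 without the 2 pools whose detected genes were over 3 MAD from the median and 175 with the run block and the ganglion cell covariate (138 shared). Genes higher in KO were 49.1% of the calls, and 45.5% to 47.4% under the other scalings; they were 66.7% without pools 1 to 12, 38.2% without pools 13 to 18 and 62.7% on 6 means. By camera 8 lists passed. The lists that passed were 0 with an estimated correlation, 0 with fry's directional test and 13 with its test of mixed directions (4 of them among the 8). With the run block 2 passed (2 of them among the 8), by over-representation 4 (1 among the 8) and on 6 means 5 (4 among the 8). The estimated correlation of the 8 lists ran from 0.069 (FGF and growth factor list) to 0.551 (ganglion cell list), above the preset 0.01. Camera calls at the preset, also with the run block and on 6 means, thus treat the genes of a list as nearly independent. For the other tests the cause was not tested. Under each of 3 scalings 6 passed, with no change of sign in the median of the 8. Among the other named genes no call reversed in 1020 planned comparisons, 110 of which lost a call. In added settings Slc18a3 (0.13) and Tshz3 (0.0305) reversed in pools 13 to 18 alone and Cdh6 (0.0704) in pools 19 to 26 alone; the cause was not tested. 7 named genes lay near the threshold and lost their call without single pools: Maml3 without any 1 of 22 pools, Cacng5 of 18, Ccdc85c of 17, Ache of 16, Th and Grm8 of 14 and Cdh6 of 11, with adjusted p up to 0.0959. Irx4, Foxn4, Th, Ache, Cacng5 and Ccdc85c also lost theirs with an offset of 0.1 TPM. No paired analysis was possible because the labels number the pools from 1 to 26 and no number occurs in both genotypes, so single pools have no partner; the 6 means matched the genotypes by run only. Changes of 0.5 on the log2 scale were recovered for 11.6% of simulated genes, so many changes of that size can be missed, and the unknown depth limits what a value near 0 TPM can show.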

Other observations

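The tests of lower starburst cell numbers, of the runs for Chat, of the ganglion cell covariate, of its reliability and of sex for the ganglion cell genes were chosen after the results were seen, and the tests of TPM shares and of the correlation with ganglion cell genes were written before. Around Fezf1, 50 tested genes lie within 10 Mb, and 3 of them changed, namely Cftr, Gpr37 and Grm8, against 1.81% of all placed genes. Cftr lies 4.92 Mb from Fezf1. These genes were picked by position after the values were seen, and no explanation was tested.

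The KO pools held more of most ganglion cell genes, with Isl2 at 20.7 TPM against 7.51, while Nefm at 68.2 against 88.5 and Pou6f2 at 182 against 266 went the opposite way; some of the 14 genes are also expressed outside ganglion cells and the labels do not give the gate. RNA of ganglion cells as the whole cause of the genes higher in KO is argued against by the covariate, with which the 109 higher genes kept a median of 96.6% of their change and the 113 lower genes 95%. A noisy covariate keeps more of a change, but the reliability of this mean within genotype and run was 0.927 (Cronbach's alpha), and correcting for it gave 96.3%; whether the mean of the 14 genes measures all ganglion cell RNA was not tested. For the 41 higher genes that lost their call it cannot be told apart, because their median correlation with the ganglion cell genes was 0.171 (-0.20 to 0.89), between the limits set for either answer; they kept 86% (median log2 change 1.16 before and 0.94 after, SE 0.27 and 0.31), so a smaller change and a larger SE ended the calls, and the 43 lower genes that lost theirs kept 89.9%. Sex is argued against as a cause of the higher ganglion cell genes, since the difference was 1.28 in pools 19 to 26, where the sexes were exchanged, and a change of ganglion-type genes within starburst cells stays open and may be related to genotype.

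The lower cholinergic genes were weighed against a lower share of starburst cells in the KO pools. That share would lower all genes of these cells. The median log2 change of Isl1, Sox2, Megf10 and Megf11 was -0.05 where Chat changed by -1.20. These genes were picked after their values were seen, and Isl1 is also in the bipolar cell list, so they cannot decide the question. Over the 10 tested starburst cell genes, fixed beforehand, the median was -0.14, while Slc18a3 and Slc10a4 fell by 0.63 and 0.53. An equal fall of the whole list was not seen, and a smaller loss of starburst cells stays open. A shift shared by all pools of a run cannot give the fall of Chat, because each run held as many KO as Het pools. The log2 change of Chat was -1.20 with the run as a block as well. Chat was lower in KO in each run, the smallest fall being -0.69, while Slc18a3 was not lower in pools 13 to 18. The falls within runs show only that the direction of Chat held. Without pools 1 to 12, and with genotype alone in the model, the call of Chat was lost (log2 change -0.84, SE 0.24, limma unadjusted p = 0.00288, adjusted p = 0.184). Abundant transcripts that take a share of the TPM are argued against because Chat kept 102% of its change after scaling by the upper quartile. A lower level of cholinergic transcripts in the cells lacking Fezf1 is a candidate explanation, and others are not excluded. These data, at a single age and without a stated sorting gate, did not test it.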
